A study of Homo sapiens with 10 samples.

How the data were processed

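H3K27ac ChIP-seq was measured in 8 libraries of HepG2 cells, at 0 h, 2 h, 8 h and 23 h of IL1B with 2 replicates each, beside 1 input sample and 1 promoter capture Hi-C sample, 10 samples in all. Per the labels, the antibody was against H3K27ac and the 0 h cells were untreated. Samples were grouped by the time in their labels. The input sample has no values of its own here and enters only through the peak lists.

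The deposited peak lists are in the format of HOMER findPeaks, 1 list per library, from reads that the authors mapped with Bowtie (version not given) to hg19. The deposited lists give a whole-number tag count for each called peak (total tags). Per the file headers, the normalized tag count of a peak is a signal scaled to 10000000 tags per library, and the control tags are a signal of the input scaled to the ChIP library. Per the file headers, the lists also hold the fold (ratio) of ChIP over input, the score of the peak caller, and a p-value against the control. Parameter lines are present for 23 h replicate 2 alone. There the authors called histone-style peaks with a peak size of 500 bp, a minimum distance of 1000 bp, at most 1 tag per bp, 4-fold over input and over the local 10000 bp, and a Poisson p of 1e-04 over input. The lowest fold over input of each list lies between 4.0 and 4.09, and the parameters of the other lists are not given. The deposited capture Hi-C list gives pairs of fragments with an interaction score of 5 or more, on GRCh37 (hg19); the caller of the interactions is not given in the labels used. The first fragment of each pair was taken as the captured one, because 12904 distinct fragments stand first and 55868 second.

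Total tags per library were read from the header for 23 h replicate 2 and derived for the others from the ratio of normalised to total tags; they ran from 2932802 to 9997397, with 1398009 to 4515432 tags in peaks. Derived totals are approximate in their last digits. A peak held a median of 16 to 29 tags. The intervals given for shares cover counting error only.

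Peaks on chromosomes 1 to 22 and X were merged across the 8 lists where they overlapped by at least 1 bp, and 495 peaks on Y were left out. The value of a region in a library is the sum of the tags of the peaks called in it, so it moves with the called length, and the called length and tags per kb are given beside each fold. Regions with a peak in all 8 libraries (17974) were tested, since a region without a call has no value in a peak list. The counts were fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, library totals as depth, TMM scaling, time as a factor and all 8 libraries in 1 fit, and p-values were adjusted by Benjamini-Hochberg at 5% within each comparison. TMM factors ran from 0.88 to 1.175, the biological coefficient of variation was 0.182, and the fit had 4 residual degrees of freedom. The SE of a log2 fold change is its size over the square root of the F statistic. CPM are tag counts over the TMM-scaled library total.

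The groups, the tests, the rule for named regions and most alternatives were fixed before the data were examined. The named regions of each time are the 8 higher and 8 lower regions with the largest log2 fold change among those past the threshold whose 2 treated libraries both lie above, or both below, both 0 h libraries, and the 4 gained and 4 lost regions with the highest normalised tags. Contacts within a chromosome and at least 20 kb apart were compared with the position mirrored on the other side of the captured fragment by McNemar's exact test. Overlap of changed regions with contact partners was tested by Fisher's exact test, two-sided, on the 22 autosomes with contacts. Noise of the shared 0 h libraries was simulated 20 times. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

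The fit was tested on simulated data with 200 changed regions among 17974. It recovered 4.5%, 10.4% and 9% of 1.5-fold changes, 25.4%, 22.4% and 37.3% of 2-fold changes, and 78.8%, 66.7% and 66.7% of 4-fold changes at 2 h, 8 h and 23 h, with 4%, 5.7% and 5.1% wrong calls. The simulations gave 75, 70 and 79 calls, against 3054, 1345 and 2313 in the data. Fewer calls make the Benjamini-Hochberg threshold stricter, so these shares may understate recovery in the data. The 2 h simulation was repeated with libraries 10 times as deep and with 4 libraries per time. The contact test was checked on 2000 simulated contacts. With 40% of partners placed on peaks it gave 43.8% against 8.73%, and with 0% placed 7.45% against 6.8% (exact McNemar test, p = 0.452).

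Alternatives were scaling by total tags alone, DESeq2 1.42.0, limma 3.58.1 on log2 summed normalised tags, tags per kb of called peak, the 4 libraries compared alone, regions called in at least 2 libraries with absent calls at the 5th percentile of the library's tags per kb, merging within 1 kb, peaks above the median strength of each list, a replicate block, an adjusted p of 10%, and leaving out each library. The fits of the 4 libraries compared and those without a library tested all regions called in the libraries kept, so more than 17974. For gained and lost regions the alternatives were lists of equal length, merging within 1 kb and peaks above the median. A 50% overlap and a replicate block were used there too. For contacts they were a distance of 100 kb, scores above the median, other peak sets, random listed fragments at the same distance, and matching on length in 10 bins. The comparison of 23 h with 2 h, all alternatives to the differences between treated times, the strongest peak per library, the overlap with captured fragments, the overlap of times with a separate 0 h library for each, the exchange of libraries between picking and measuring, the comparisons with a separate 2 h library for each and their simulations, and the repeated 2 h simulations were added after the data were seen.

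The gene table at hand is not on hg19 and no hg19 genome was used here, so regions are named by position. The lists of genes and the searches for transcription factor motifs that had been planned were not run, and no region is assigned to a gene.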

Results

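The series profiled H3K27ac, a histone mark carried by active promoters and enhancers, in HepG2 cells, a human hepatoma line used as a model of hepatocytes. ChIP-seq libraries were made from untreated cells (0 h) and from cells treated with IL1B, an inflammatory cytokine, for 2 h, 8 h and 23 h. Each of the 4 time points has n = 2 libraries, 8 in all, and a single promoter capture Hi-C library without a replicate gives the contacts of captured promoter fragments. By the title of the series, its subject is noncoding regulatory variation in liver that bears on the risk of coronary artery disease.

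The 0 h libraries held 6152528 and 9572784 tags for replicates 1 and 2. The 2 h libraries held 9645463 and 9900886 tags and the 8 h libraries 7784858 and 9997397. The 23 h libraries held 8193840 and 2932802 tags, so 23 h replicate 2 was the shallowest of the 8. Peaks numbered 44888 and 50017 at 0 h and 45818 and 49947 at 2 h. They numbered 45618 and 46955 at 8 h and 44500 and 33848 at 23 h. Between 35.11% (0 h replicate 1) and 47.67% (23 h replicate 2) of tags lay in peaks. The median fold over input of the peaks was 22.88 in 23 h replicate 2 and between 9.6 and 12.73 in the other libraries.

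Merging the peaks of the 8 lists gave 95046 regions, of which 46155 had a peak in 1 library and 17974 had a peak in all 8. These 17974 regions, with a median length of 3646 bp, were tested for a change. They held between 87.25% and 92.58% of each library's tags in peaks. Across regions, log2 levels of the replicates correlated with r = 0.937 at 0 h, 0.947 at 2 h, 0.948 at 8 h and 0.874 at 23 h. Libraries of different times correlated with r between 0.812 and 0.934. Regions are not independent replicates. On average 68.08% of the peaks of a library overlapped a peak of the other replicate, against 66.94% for libraries of different times. The peak lists alone thus set the times apart by little. Region levels are TMM-scaled CPM summed over the peaks called in the region. They are given as mean ± SD of n = 2 libraries. Positions are on the human build hg19, counted from 1.

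The comparison of 2 h with 0 h asks where H3K27ac changed early in the response to IL1B. The largest increase was at chr2:228656989–228668034, from 1.85 ± 0.53 to 51.9 ± 0.465 CPM (log2 fold change 4.73, SE 0.45, adjusted p = 2.34e-05). Its called length went from 0.82 to 10.48 kb and its mean level from 2.45 to 4.95 CPM per kb. At chr14:35609963–35617707 the level rose from 3.02 ± 1.13 to 41.1 ± 7.02 CPM (log2 3.69, SE 0.25, adjusted p = 1.99e-06). Called length there went from 0.75 to 6.98 kb, at 4.13 and 5.89 CPM per kb. The other 6 of the 8 named increases had log2 fold changes between 3.19, at chr2:109208622–109213306, and 3.60, at chr8:128893930–128900302. The largest decrease was at chr16:10421140–10427824, from 11.2 ± 1.52 to 1.59 ± 0.395 CPM (log2 -2.82, SE 0.47, adjusted p = 0.00139). The called length went from 3.79 to 0.8 kb, at 3.08 and 2.17 CPM per kb. The level at chr4:106955824–106959895 fell from 16.3 ± 0.225 to 2.46 ± 0.996 CPM (log2 -2.72, SE 0.34, adjusted p = 0.000212). This decrease took the called length from 3.73 to 1.1 kb, at 4.37 and 2.22 CPM per kb. The 8 named decreases lay between -2.82 and -2.66.

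Across the 17974 regions, 1497 were higher and 1557 lower at 2 h than at 0 h, or 16.99%. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 5%. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical. Higher regions had a median log2 fold change of 0.99, and 732 of them changed at least 2-fold. Lower regions had a median of -0.91, and 664 changed at least 2-fold. Regions that rose had a median 0 h level of 13.41 CPM and regions that fell one of 28.8 CPM, against 9.31 CPM for regions that did not pass. The 0 h level enters the fold that sets these classes, and regions that lose their peak are not tested. The higher level of regions that fell may follow from that. The median called length of higher regions went from 2.84 to 4.81 kb, with a median log2 change of 0.44 in tags per kb. That of lower regions went from 4.55 to 3.53 kb, with -0.40 in tags per kb. Tags per kb moved in the direction of the sum in 95.1% of the higher and 96.5% of the lower regions. The regions were called on the sum, which is tags per kb times called length in the same libraries. Picking on the sum thus favours a like direction in tags per kb, and these shares and medians are no separate evidence. Tested on tags per kb with limma, 193 regions passed (125 higher, 68 lower), with 3 of the 8 named increases and none of the 8 named decreases among them. The strongest peak per library gave 1614, depth scaling alone 2035 (1013 higher, 1022 lower), and a fit of the 4 libraries compared 4590. That fit and those without a library tested all regions called in the libraries kept, which adds regions to the 17974. The count was 1431 or 1404 without 0 h replicate 1 or 2, and 1388 or 1453 without 2 h replicate 1 or 2, each with more higher than lower regions. It was 4698 or 4779 without 23 h replicate 1 or 2.

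**Figure D1:**
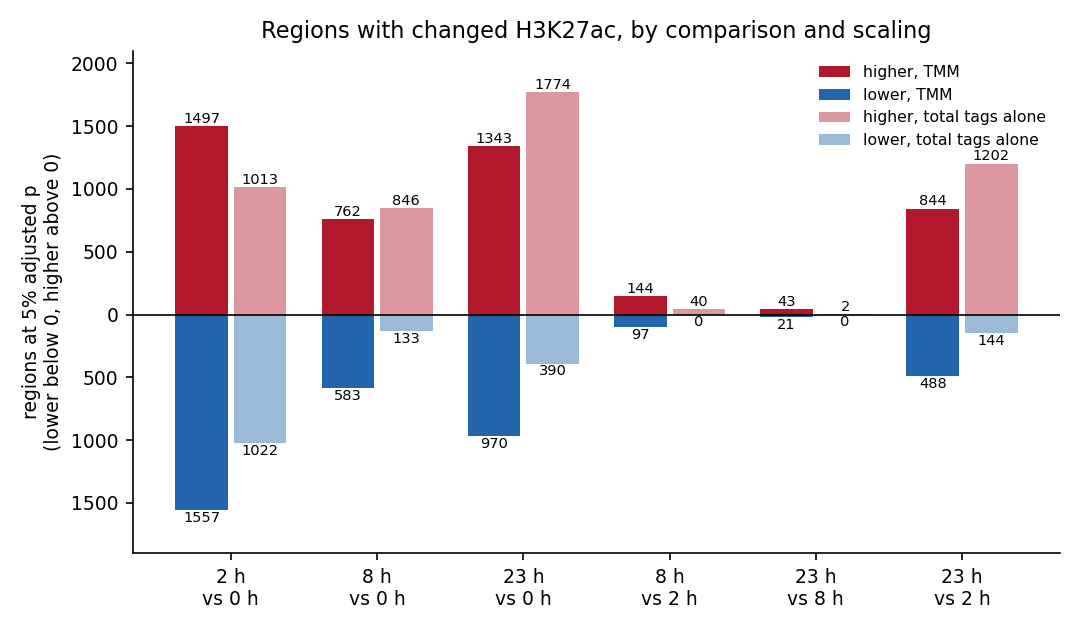
Number of regions (y axis) with higher H3K27ac, above 0, and lower H3K27ac, below 0, at an adjusted p of 5% for each comparison of times, with TMM scaling (dark bars) and with depth scaling alone (pale bars). With TMM the counts were 1497 and 1557 at 2 h, 762 and 583 at 8 h, and 1343 and 970 at 23 h, and with depth alone 846 and 133 at 8 h and 1774 and 390 at 23 h.

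The comparison of 8 h with 0 h asks which changes were present later in the treatment. At chr2:228656989–228668034 the level was 31.8 ± 7.48 CPM at 8 h (log2 4.02, SE 0.46, adjusted p = 0.000235). The called length was 6.75 kb against 0.82 kb at 0 h, at 4.73 and 2.45 CPM per kb. At chr1:206641476–206648319, which overlaps a captured promoter fragment, H3K27ac rose from 2.45 ± 1.64 to 34.3 ± 4.09 CPM (log2 3.66, SE 0.30, adjusted p = 2.04e-05). Its called length went from 1.03 to 5.09 kb, at 2.45 and 6.74 CPM per kb. The region chr1:32419464–32422770, also on a captured fragment, rose from 2.58 ± 0.252 to 22.1 ± 0.684 CPM (log2 3.07). Over that span the called length went from 0.76 to 3.04 kb, at 3.75 and 7.25 CPM per kb. The largest decrease was at chr20:49291445–49297830, from 20.4 ± 0.106 to 2.11 ± 1.5 CPM (log2 -3.20, SE 0.42, adjusted p = 0.000773). There the called length went from 5.47 to 1.08 kb, at 3.80 and 2.00 CPM per kb. The level at chr2:62715739–62720407 fell from 11.96 ± 0.19 to 1.6 ± 0.146 CPM (log2 -2.90). Called length there went from 3.32 to 0.57 kb, at 3.71 and 2.87 CPM per kb.

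At 8 h 762 regions were higher and 583 lower than at 0 h, or 7.48% of those tested (edgeR, adjusted p of 5%). Their median log2 fold changes were 1.01 and -0.87. At least 2-fold changes numbered 382 up and 221 down. Median called length went from 2.95 to 4.82 kb in higher and from 5.11 to 3.86 kb in lower regions. Median log2 changes in tags per kb were 0.44 and -0.37. With depth scaling alone the median log2 fold change of all regions was 0.191, against 0.011 with TMM. It gave 846 higher and 133 lower regions, 86.4% higher against 56.7% with TMM. On tags per kb 25 regions passed with limma (23 higher, 2 lower), with 3 of the 8 named increases and none of the 8 named decreases among them. The strongest peak per library gave 394 (281 higher, 113 lower) and a fit of the 4 libraries compared 3087. The count was 378 (288 higher, 90 lower) or 412 (304 and 108) without 0 h replicate 1 or 2. It was 352 (271 and 81) or 307 (218 and 89) without 8 h replicate 1 or 2, so the share of higher regions was between 71.0% and 77.0% in these 4 fits. Without 23 h replicate 1 or 2 it was 2837 or 2864. Without 8 h replicate 2 the call ended at 6 of the 8 named decreases, but not at the 2 given here.

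The comparison of 23 h with 0 h asks which changes were present after the longest treatment. At chr6:157879794–157884207 H3K27ac was 1.55 ± 0.687 CPM at 0 h, 15.9 ± 0.006 at 2 h, 17.2 ± 0.22 at 8 h and 17.7 ± 0.023 at 23 h (23 h log2 3.60, SE 0.32, adjusted p = 3.67e-05). Its called length went from 0.57 to 2.52 kb at 23 h, at 2.66 and 7.78 CPM per kb. At chr11:86451526–86454398 the level was 1.34 ± 0.061 CPM at 0 h, 4.05 ± 0.638 at 2 h, 7.02 ± 0.457 at 8 h and 12.7 ± 3.42 at 23 h (23 h log2 3.20, SE 0.43, adjusted p = 0.000515). Called length there went from 0.56 to 2.37 kb at 23 h, at 2.39 and 5.63 CPM per kb. At chr2:228656989–228668034 the 23 h libraries differed, with 28.0 CPM in replicate 1 and 8.42 in replicate 2. The log2 fold change was 3.35 (SE 0.48, adjusted p = 0.000793), with a called length of 0.82 and 3.56 kb at 2.45 and 4.92 CPM per kb. The largest decrease was at chr4:79118313–79124254, from 15.1 ± 2.80 CPM at 0 h to 2.06 ± 1.20 at 23 h (log2 -3.04, SE 0.45, adjusted p = 0.000932). The called length went from 4.49 to 0.58 kb, at 3.59 and 3.41 CPM per kb. The level at chr17:36187287–36191713 fell from 22.3 ± 2.53 to 3.54 ± 2.79 CPM (log2 -2.89, SE 0.43, adjusted p = 0.00103). Over that span the called length went from 3.25 to 1.07 kb, at 7.00 and 3.03 CPM per kb.

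At 23 h 1343 regions were higher and 970 lower than at 0 h, or 12.87% of those tested (edgeR, adjusted p of 5%). Their median log2 fold changes were 0.98 and -1.03. At least 2-fold changes numbered 660 up and 497 down. Median called length went from 2.97 to 3.98 kb in higher and from 4.45 to 2.57 kb in lower regions. Median log2 changes in tags per kb were 0.43 and -0.40. With depth scaling alone the median log2 fold change of all regions was 0.258, against 0.043 with TMM. It gave 1774 higher and 390 lower regions, 82.0% higher against 58.1% with TMM. On tags per kb 106 regions passed with limma (80 higher, 26 lower), with 3 of the 8 named increases and 1 of the 8 named decreases, chr17:36187287–36191713, among them. The log2 change of another named decrease, chr5:172723414–172729649, was -2.68 in the sum and 0.014 in tags per kb, and its call ended without 0 h replicate 1. The strongest peak per library gave 1227 (644 higher, 583 lower) and a fit of the 4 libraries compared 1226. The count was 949 or 924 without 0 h replicate 1 or 2. Without 23 h replicate 1 it was 3865, with 1943 higher and 1922 lower, a smaller excess of higher regions. That fit gives the lone 23 h library the spread of the other times. The 23 h libraries differed more between replicates, with a chi-square over regions of 5.78 per degree of freedom against 2.88 to 3.25 at the other times.

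**Figure D2:**
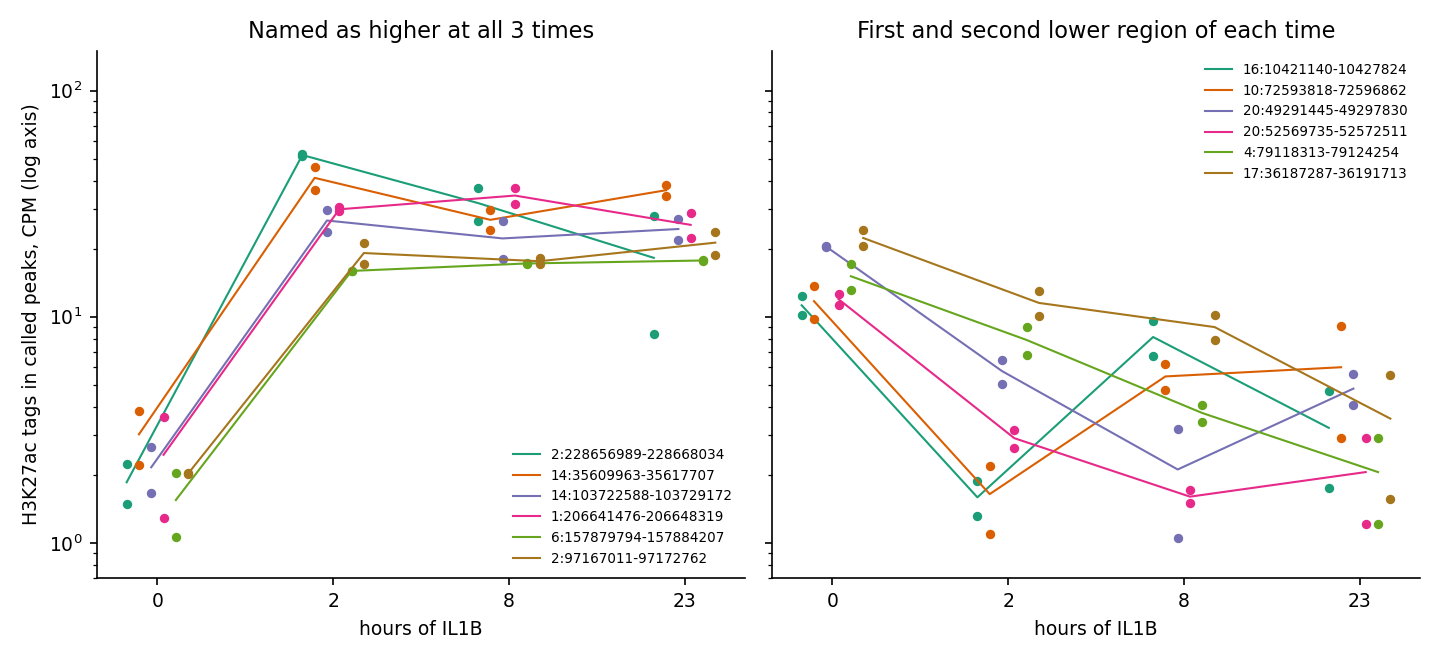
H3K27ac level in CPM (log axis) by hours of IL1B for the 6 regions among the largest increases at all 3 times (left) and the first and second largest decreases of each time (right); points are the 2 libraries of each time and lines join their means. The level at chr2:228656989–228668034 goes from 1.85 CPM at 0 h to 51.9 at 2 h, and that at chr16:10421140–10427824 from 11.2 to 1.59.

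Of the 8 largest increases named at each time, 6 regions were among the largest at 2 h, 8 h and 23 h alike, and 7 at both 8 h and 23 h. Of the 8 largest decreases, none of those at 2 h was among those at 8 h or 23 h. The 2 shared by 8 h and 23 h were chr20:52569735–52572511, whose 8 h call ended without 8 h replicate 2, and chr2:62715739–62720407. The named decreases of 2 h had negative log2 fold changes later too, of -2.00 to -0.48 at 8 h and -1.89 to -0.34 at 23 h. Most of these did not pass. At 8 h only chr1:145718987–145721639 and chr1:62705971–62709371 passed against 0 h (edgeR, adjusted p = 0.0121 and 0.0330). At 23 h only chr1:145718987–145721639 and chr16:10421140–10427824 did (0.0132 and 0.0265). The 0 h libraries that picked these regions also enter the later folds, so their noise alone favours a negative sign. Only regions called in all 8 libraries are ranked, so complete losses are left out. Across all tested regions, 520 were higher at each of the 3 times and 282 lower at each. Regions higher at both 2 h and 8 h numbered 631, where independent calls would give 63.5, and regions lower at both numbered 425 against 50.5. The numbers for independent calls, here and below, give every region the same chance of a call. Broad regions were called more often: 20.5% of those of 10 kb or more were higher at 2 h, against 6.8% under 2 kb. Part of the excess may come from that. No region was higher at 2 h and lower at 8 h or the reverse. For 2 h and 23 h 730 were higher and 488 lower at both, and 23 had opposite calls. The same 0 h libraries enter each comparison. Across regions the log2 fold changes at 2 h and 8 h correlated with r = 0.766, against 0.519 in 20 simulations with shared 0 h libraries and no change. At 2 h and 23 h they correlated with 0.647 against 0.496. The overlap was therefore also counted, after the data were seen, with each time compared against a different 0 h library, so that none was shared. Regions higher at both 2 h and 8 h then numbered 205 or 217, by which 0 h library went with which time, where independent calls would give 11.4 or 12.3. Regions lower at both numbered 56 or 72 against 2.9 or 3.9, and the log2 fold changes correlated with r = 0.515 or 0.523. For 2 h and 23 h 294 or 301 were higher at both against 25.6 or 24.4, 117 or 121 lower against 11.2 or 11, and r was 0.435 or 0.459. Opposite calls at 2 h and 23 h then numbered 3 or 6.

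Direct comparison of the treated times asks where the response differed with time. At chr20:3519152–3529805 the level was 57.3 ± 1.82 CPM at 0 h, 28.3 ± 2.35 at 2 h, 34.3 ± 0.314 at 8 h and 103.6 ± 1.53 at 23 h. It differed between 23 h and 8 h by a log2 of 1.59 (SE 0.11, adjusted p = 3.92e-05), with called lengths of 9.62 and 5.35 kb at 10.8 and 6.44 CPM per kb. At chr20:32274467–32278343 the level rose from 1.04 ± 0.073 CPM at 2 h to 6.67 ± 0.534 at 8 h (log2 2.67, SE 0.41, adjusted p = 0.0138), and was 16.1 ± 3.41 CPM at 23 h. Its called length went from 0.5 kb at 2 h to 2.54 kb at 8 h, at 2.08 and 2.62 CPM per kb. The 2 h decrease at chr16:10421140–10427824 was followed by 8.13 ± 2.03 CPM at 8 h (log2 2.34 against 2 h, adjusted p = 0.0351). Called length there went from 0.8 to 3.18 kb, at 2.17 and 2.59 CPM per kb. At 23 h it was 3.22 ± 2.1 CPM, lower than at 0 h (log2 -1.68, adjusted p = 0.0265). The difference of 23 h passed neither against 8 h (log2 -1.20, adjusted p = 0.307) nor against 2 h (log2 1.13, adjusted p = 0.204). In the other direction chr15:50834171–50836304 fell from 6.73 ± 1.13 CPM at 2 h to 1.49 ± 0.116 at 8 h (log2 -2.17, adjusted p = 0.043). The called length went from 2.09 to 0.64 kb, at 3.22 and 2.48 CPM per kb. At 23 h it was 4.53 ± 0.25 CPM, a difference that passed neither against 2 h (log2 -0.56, adjusted p = 0.491) nor against 8 h (log2 1.61, adjusted p = 0.18). With depth scaling alone the call at chr15:50834171–50836304 ended (log2 -1.99, adjusted p = 0.0735), and the other 3 passed. On tags per kb (limma) none of the 4 passed, with log2 differences of 0.45 at chr20:3519152–3529805, 0.32 at chr20:32274467–32278343, 0.23 at chr16:10421140–10427824 and -0.43 at chr15:50834171–50836304. The 3 calls between 8 h and 2 h also ended without 2 h replicate 1 or 2 and without 8 h replicate 1 or 2 (adjusted p between 0.115 and 0.352), and that at chr20:3519152–3529805 did not. The strongest peak per library ended these 3 calls too. The calls at chr16:10421140–10427824 and chr15:50834171–50836304 ended without 0 h replicate 1 or 2, with the replicate block and with limma on summed tags too (adjusted p between 0.0593 and 0.0909). DESeq2 gave no adjusted p for the 3 calls. These regions, other than chr16:10421140–10427824, were chosen for the size of the difference after their values were seen.

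Between 8 h and 2 h 144 regions were higher and 97 lower, and between 23 h and 8 h 43 and 21 (edgeR, adjusted p of 5%). Between 23 h and 2 h, a comparison added after the data were seen, 844 were higher and 488 lower. With the replicate numbers as a block the counts of the 3 comparisons were 31, 9 and 920. Of the regions lower at 2 h than at 0 h, 122 were higher at 8 h than at 2 h and 420 were higher at 23 h than at 2 h. Of those higher at 2 h, 78 were lower at 8 h than at 2 h and 232 lower at 23 h than at 2 h. These comparisons share the 2 h libraries. In 20 simulations with 1 level for 2 h, 8 h and 23 h, at most 3 regions went either way. The simulations draw each library independently, so they cannot show what a handling difference shared by the libraries of a time would give. With 1 of the 2 h libraries set against 0 h and the other against the later time, 1 region was lower at 2 h and higher at 8 h, and 83 or 80 were lower at 2 h and higher at 23 h. Higher at 2 h and lower later were then 0 or 1 region at 8 h and 43 or 34 at 23 h. For 8 h this split cannot decide, since with 1 library at 2 h hardly any region differed between 8 h and 2 h at all. The class lower at 2 h had median log2 ratios to 0 h of -0.91, -0.49 and -0.44 at 2 h, 8 h and 23 h. The class higher at 2 h had 0.99, 0.66 and 0.68. Picked for an at least 2-fold decrease at 2 h in the libraries numbered 1, 1523 regions had medians of -0.84, -0.56 and -0.66 in the libraries numbered 2. Picked in the libraries numbered 2, 1344 regions had medians of -0.90, -0.54 and -0.45 in those numbered 1, so whether 23 h lay nearer to 0 h than 8 h differed between both choices.

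In the order 8 h against 2 h, 23 h against 8 h and 23 h against 2 h, 0 regions passed on tags per kb in each comparison (limma). At an unadjusted p under 0.05 were 1257, 1634 and 2489. On summed tags DESeq2 gave 325, 135 and 1192 and limma 96, 23 and 1300, and the strongest peak per library gave 5 (1 higher, 4 lower), 4 (1 higher, 3 lower) and 245 (122 higher, 123 lower). Depth scaling alone in edgeR gave 40 higher and 0 lower regions between 8 h and 2 h, with 2388 at an unadjusted p under 0.05. It gave 2 higher and 0 lower between 23 h and 8 h, with 1566 at an unadjusted p under 0.05. Between 23 h and 2 h it gave 1202 higher and 144 lower, 89.3% higher against 63.4% with TMM. The median log2 fold change of all regions there was 0.244 with depth alone and 0.03 with TMM, and for 8 h against 2 h it was 0.183 and 0.002. For 8 h against 2 h the count was 30 or 34 without 0 h replicate 1 or 2 and 1 or 4 without 2 h replicate 1 or 2. It was 2 without either 8 h library, and 1088 or 1107 without 23 h replicate 1 or 2. For 23 h against 8 h it was 11 or 10 without 0 h replicate 1 or 2 and 25 or 24 without 2 h replicate 1 or 2. Without 8 h replicate 1 or 2 it was 1 or 2, and without 23 h replicate 1 or 2 it was 1156 (499 higher, 657 lower) or 180 (122 higher, 58 lower). For 23 h against 2 h it was 882 without 0 h replicate 1 and 305 or 273 without 2 h replicate 1 or 2. Without 8 h replicate 1 or 2 it was 839 or 790, and without 23 h replicate 1 it was 2904, with 1409 higher and 1495 lower. The excess of higher regions at 23 h over 2 h and over 8 h was thus reversed in the fits without that library, which give the other 23 h library the spread of the other times.

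**Figure D3:**
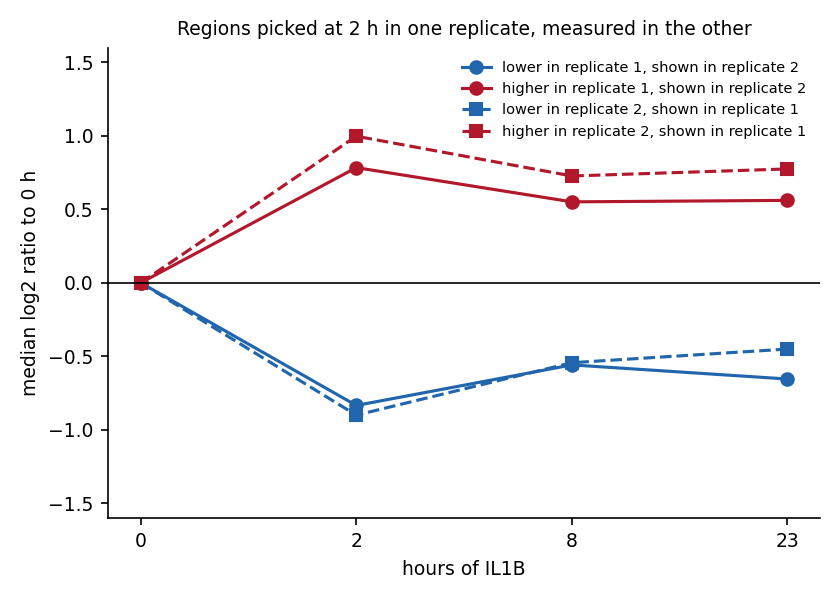
Median log2 ratio to 0 h (y axis) by hours of IL1B for regions picked for an at least 2-fold difference between 2 h and 0 h in the libraries of 1 replicate number, measured in the libraries of the other; red lines are regions picked as higher and blue lines as lower. Regions picked as lower in replicate 1 had medians of -0.84, -0.56 and -0.66 in replicate 2 at 2 h, 8 h and 23 h.

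Regions with a peak in both libraries of a treated time and in neither 0 h library were counted as gained, and the reverse as lost. No fold is given for them, since the absent value is unknown. The strongest gained region at 2 h was chr5:150472314–150476772, with 179.8 ± 27.2 normalised tags (per 10000000 of the library), followed by chr2:231629099–231632684 with 174.9 ± 11.2, which was also the strongest at 8 h with 223.9 ± 24.2. At 23 h the strongest were chr6:133053685–133058829 with 331.8 ± 75.7 and chr16:11298147–11302698 with 313.2 ± 20. The strongest region lost at 2 h was chr20:43088567–43091153, with 131.1 ± 0.8 normalised tags at 0 h, and it had peaks again in all 4 libraries of 8 h and 23 h. At 8 h it was chr16:77782287–77784470 with 78.4 ± 7.4, and at 23 h chr11:3979172–3983903 with 123.3 ± 50.2.

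Gained and lost regions numbered 2539 and 1864 at 2 h, 2160 and 1680 at 8 h, and 1114 and 2751 at 23 h. At all 3 times 305 were gained and 703 lost. With 2 libraries a side a comparison has 3 splits of its 4 libraries, too few for a test. The split by time gave 4403, 3840 and 3865 regions in all at 2 h, 8 h and 23 h, and the larger of the other splits 2805, 2930 and 2927. Counted in 1 direction, the other splits gave up to 2043, 2198 and 2602 regions. That is more than the 1864 lost at 2 h, the 2160 gained and 1680 lost at 8 h and the 1114 gained at 23 h, and fewer than the 2539 gained at 2 h and the 2751 lost at 23 h. With lists of equal length 1014 were lost at 8 h, and 1357 were gained and 1502 lost at 23 h, where replicate 2 has the shortest list. With peaks above the median strength of each list, 1278 and 937 were gained and lost at 2 h, 1035 and 855 at 8 h, and 432 and 1540 at 23 h. Leaving out a library asks for 3 agreeing lists in place of 4. The gained count at 2 h was then 13078 or 10190 without 2 h replicate 1 or 2 and 5246 without 0 h replicate 2. At 8 h it was 10508 or 10214 without 8 h replicate 1 or 2 and 4705 without 0 h replicate 2. At 23 h it was 5352 or 8684 without 23 h replicate 1 or 2 and 2605 without 0 h replicate 2. The lost count at 2 h was 3068 or 3320 without 2 h replicate 1 or 2 and 12233 or 9374 without 0 h replicate 1 or 2. At 8 h it was 2589 or 3452 without 8 h replicate 1 or 2 and 12190 or 9291 without 0 h replicate 1 or 2. At 23 h it was 6643 without 23 h replicate 1 and 14625 or 11018 without 0 h replicate 1 or 2.

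The promoter capture Hi-C list held 86474 contacts between 12904 captured fragments and 55868 partner fragments. Of these 99.74% lay within a chromosome, at a median distance of 182.5 kb. Partner fragments overlapped regions with H3K27ac peaks in both 0 h libraries in 25.42% of 80506 contacts at least 20 kb apart. The position mirrored on the other side of the captured fragment did so in 12.45%, a ratio of 2.041. Where only 1 of the pair overlapped, it was the partner in 17021 contacts and the mirrored position in 6582 (72.11%, 95% exact interval 71.54 to 72.69). By McNemar's exact test, two-sided, p was below 1e-300. Contacts share fragments, so the interval covers counting error only. Against a fragment drawn at random from those listed at the same distance, the shares were 25.95% and 22.41%, a ratio of 1.158. In 15.92% of all listed contacts the partner was itself a captured fragment. These contacts were kept, and their part in the ratios was not tested.

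Of all tested regions on chromosomes with contacts, 41.29% overlapped a partner fragment. Of the 8 named increases 2 did so at each time, and of the 8 named decreases 3, 3 and 6 at 2 h, 8 h and 23 h. The regions given next are examples from these, and do not show that the largest changes have more contacts. The region with the largest increase, chr2:228656989–228668034, contacts a captured fragment at chr2:228332065–228338268 with a score of 8.45 over 327.3 kb. The region chr14:35609963–35617707 contacts 3 captured fragments, the best at chr14:35738717–35758063 with a score of 12.4. The region chr16:10421140–10427824, lower at 2 h, contacts 4 captured fragments, the best at chr16:10588447–10591525 with a score of 15.92. Of regions lower at 8 h and at 23 h, 49.22% and 48.64% overlapped a partner fragment, against 41.01% and 40.73% of those that did not pass. The odds ratios were 1.394 (95% interval 1.181 to 1.647) and 1.378 (1.209 to 1.571). For regions lower at 2 h the share was 44.42% and the odds ratio 1.157 (1.04 to 1.287). For regions higher at 2 h, 8 h and 23 h the odds ratios were 1.061, 1.014 and 1.072.

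By Fisher's exact test, two-sided and adjusted over the 6 classes, lower regions passed (adjusted p = 0.0147 at 2 h, 0.000306 at 8 h and 1.04e-05 at 23 h). Higher regions did not (0.348, 0.879 and 0.348). The test takes regions as independent, but regions of like direction lay near each other. At 2 h 43.8% of lower regions had another 10 to 100 kb away, against 25.4% in permutations. The p-values here, for the matched values and for captured fragments may therefore be too small. Changed regions are longer, with medians of 5888 bp (higher) and 5614 bp (lower) against 3350 bp at 2 h. Matched on length in 10 bins, the odds ratios were 0.775, 0.735 and 0.805 for higher regions at 2 h, 8 h and 23 h. For lower regions they were 0.886, 1.067 and 1.099. The values below 1 passed (adjusted p between 8.7e-05 and 0.0498), and those of lower regions at 8 h and 23 h did not (adjusted p = 0.457 and 0.204). Overlap with captured fragments themselves was compared after the data were seen. On them lay 24.28%, 20.8% and 23.62% of regions higher at 2 h, 8 h and 23 h and 20.21%, 20.7% and 18.83% of those lower. Of regions that did not pass it was 36.81%, 35.43% and 36.22%. The odds ratios lay between 0.408 and 0.551, each past Fisher's exact test. The contacts come from 1 library and the labels do not tie it to a treatment time, so no contact is compared between times.

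**Figure D4:**
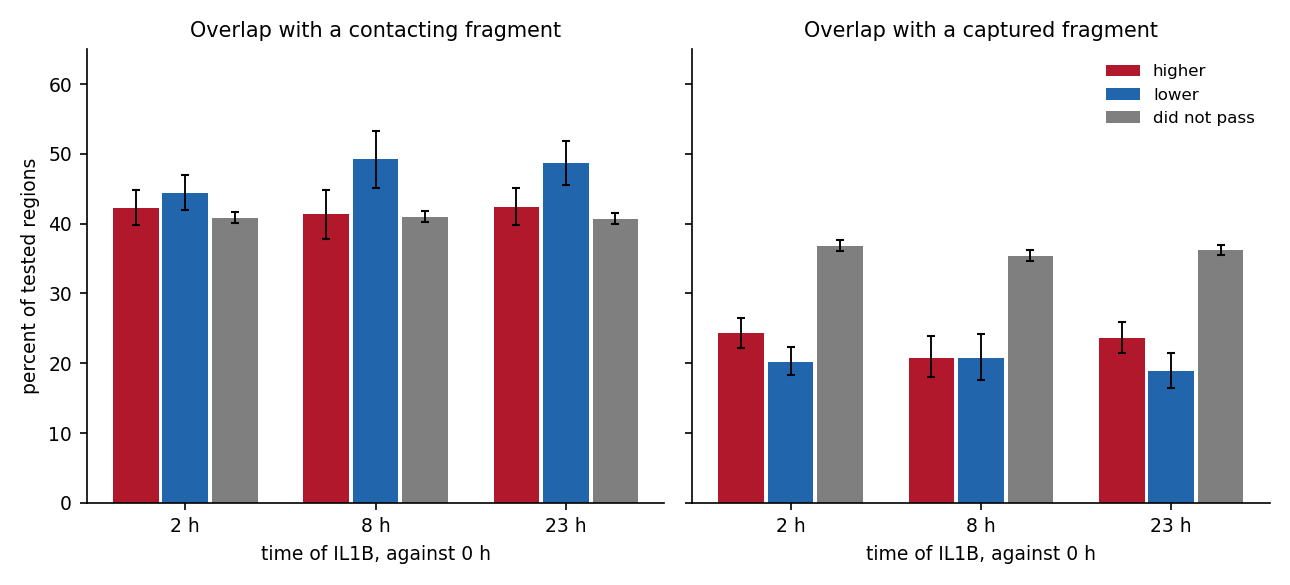
Percent of tested regions (y axis) that overlap a partner fragment of a contact (left) or a captured fragment (right), for regions higher, lower or not passing at 2 h, 8 h and 23 h; error bars are 95% Wilson intervals of counting error. Regions lower at 23 h overlap a partner fragment in 48.64% of cases against 40.73% of those not passing, and a captured fragment in 18.83% against 36.22%.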

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

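The comparison of 23 h with 2 h, all alternatives to the differences between treated times, the strongest peak per library, the test on the strongest regions with scaling by total tags alone, the exchange of libraries between picking and measuring under both scalings, and the use of peak lists of equal length as a test were chosen only after the result was seen; the lists themselves had been chosen as an alternative before.

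The change from 0 h differed between times in a direct test of the difference (edgeR's quasi-likelihood test, Benjamini-Hochberg at 5%). Between 2 h and 8 h 241 regions differed, 144 higher and 97 lower at 8 h. Between 8 h and 23 h 64 regions differed, 43 higher and 21 lower at 23 h. Between 2 h and 23 h 1332 regions differed, 844 higher and 488 lower at 23 h. With the replicate numbers as a block the counts were 31, 9 and 920, and on tags per kb 0 regions passed in each (limma; 1257, 1634 and 2489 at an unadjusted p under 0.05). Without any 1 library of 2 h or 8 h the first count was between 1 and 4. Without 8 h replicate 1 or 2 the second was 1 or 2, and without 2 h replicate 1 or 2 the third was 305 or 273. Without 23 h replicate 1 more regions were lower than higher at 23 h, 657 against 499 from 8 h and 1495 against 1409 from 2 h, in fits that give the other 23 h library the smaller spread of the other times. The strongest peak per library gave 1 higher and 3 lower, and 122 and 123, and 1 higher and 4 lower at 8 h against 2 h. Depth scaling alone gave 40 higher and 0 lower regions at 8 h against 2 h, 2 and 0 at 23 h against 8 h, and 1202 and 144 at 23 h against 2 h.

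Regions lower at 2 h lay nearer to their 0 h level at 8 h, with median log2 ratios of -0.91 and -0.49. Selection on noise in the 2 h libraries predicts no such difference in libraries that did not pick the regions, but the smaller of the 2 differences of medians was 0.276 (bootstrap interval over regions, without the spread between libraries, 0.227 to 0.317; the other was 0.357). The 0 h, 2 h and 8 h libraries can be divided between picking and measuring in 8 ways. Over these the difference lay between 0.231 and 0.387. That argues against selection on noise as the whole cause. With scaling by total tags alone the difference lay between 0.317 and 0.663. There the median of all regions was 0.183 higher at 8 h than at 2 h. Regions picked as higher came nearer to 0 h with TMM (-0.27 to -0.206), but went either way with total tags alone (-0.207 to 0.092). Their return thus depends on whether the shift of all regions, which TMM takes out, is counted. Lower ChIP enrichment at 2 h predicts that strong regions fall together. TMM could remove a joint fall, so this was tested with scaling by total tags alone, where the median log2 fold change of all regions at 2 h was 0.009. Among the changed regions of the 1798 strongest at 0 h 30.2% were higher (118, against 273 lower; exact interval 25.7 to 35), and the median of the 1798 was -0.11 with quartiles of -0.40 and 0.17. That argues against lower enrichment as the whole cause. A part in the excess of decreases among strong regions stays open. Picking the strongest regions on the 0 h libraries of the fold can add decreases there too. Of all tags 37.73% and 37.67% lay in peaks at 2 h, between the 35.11% and 39.65% of 0 h. At 8 h the shares were 38.98% and 45.17%. Whether higher enrichment at 8 h had a part in the return was not tested. A decrease that is deepest at 2 h and partly undone by 8 h stays a hypothesis, for the regions picked at 2 h alone. Picking at 2 h favours regions whose decrease is deepest then, also in libraries that did not pick. Regions lower at 8 h had medians of -0.89 at 2 h and -0.87 at 8 h. Regions lower at 23 h had medians of -0.69, -0.63 and -1.03 at 2 h, 8 h and 23 h. A shared difference in the handling of the 2 h libraries was not tested, since the labels give no batch.

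At 23 h more regions were lost (2751) than gained (1114) from the peak lists, 28.8% gained, while more tested regions were higher (1343) than lower (970). The excess of higher regions was small without 23 h replicate 1 (1943 against 1922) and on the strongest peak per library (644 against 583), so the contrast between both counts rests in part on that library, as far as the lone 23 h library of that fit varies like those of the other times. With lists of equal length 47.5% of the gained and lost regions were gained, which is consistent with the short list of the shallow 23 h replicate 2 as a source of the excess of losses. A biological loss of weak peaks at 23 h was not tested.

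Regions that changed overlapped captured fragments less often than regions that did not pass, with odds ratios between 0.408 and 0.551. Matched on the H3K27ac level in 10 bins, the highest of the 6 odds ratios was 0.499, which argues against the level as the whole cause. On the strongest peak per library the highest was 0.536, which argues against the sum over several called peaks. That the response to IL1B falls less often on promoters than on other elements may follow, as a hypothesis that rests on the first fragment of each pair being the captured one. Promoters without a listed contact are not seen here, and a smaller change that the test misses at promoters was not examined.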

How the results depend on the processing

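The comparison of 23 h with 2 h, all alternatives to the differences between treated times, and the strongest peak per library were chosen only after the result was seen. Where no cause is named below, the cause was not tested. Counts of changed regions are given in the order 2 h, 8 h, 23 h, 8 h against 2 h, 23 h against 8 h, 23 h against 2 h; unnamed ones lay within 1.5 times of 3054, 1345, 2313, 241, 64 and 1332.

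Depth scaling alone gave 2035 at 2 h, 40 for 8 h against 2 h and 2 for 23 h against 8 h. Tags per kb gave 193, 25, 106, 0, 0 and 0 (limma; 1257, 1634 and 2489 regions at an unadjusted p under 0.05 in the last 3, where edgeR gave 241, 64 and 1332 and DESeq2 325, 135 and 1192 on sums). The strongest peak gave 1614, 394, 1227, 5, 4 and 245. The 4 libraries compared alone gave 4590, 3087 and 1226. That fit and those without a library tested all regions called in the libraries kept, more than the 17974 called in all 8. Regions called in at least 2 libraries, which tests more regions, gave 530 and 386 for the first 2 differences between times. DESeq2 gave 135 for 23 h against 8 h, and limma 96 for 8 h against 2 h and 23 for 23 h against 8 h. Merging within 1 kb gave 35 and peaks above the median 29 for 23 h against 8 h. An adjusted p of 10%, looser by construction, gave 2165 at 8 h and 554, 211 and 2149 for the differences. With the replicate block in the fit the counts were 2619, 1002, 1908, 31, 9 and 920. Deviations of same-numbered libraries correlated between -0.181 and 0.037. That shows no marked effect shared by replicate number, but cannot tell whether the numbers mark paired cultures, which the labels do not say. Leaving out 1 library gave 1388 to 4779, 307 to 2864, 924 to 3865, 1 to 1107, 1 to 1156 and 273 to 2904; where a time keeps 1 library, it is assumed to vary like the others, which the larger spread at 23 h (chi-square of 5.78 per degree of freedom against 2.88 to 3.25) puts in doubt there.

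Peaks above the median, fewer by construction, gave 1278 gained and 937 lost regions at 2 h, 1035 and 855 at 8 h, and 432 and 1540 at 23 h, and lists of equal length 1014 lost at 8 h and 1502 lost at 23 h. Leaving out 1 library, which asks for fewer agreeing lists, gave 3535 to 13078 gained and 3068 to 12233 lost at 2 h, 3053 to 10508 and 2589 to 12190 at 8 h, and 1565 to 8684 and 3364 to 14625 at 23 h. The replicate block gave the counts of the comparison itself, by construction. Overlap of replicate peaks was 68.08%, 64.47% at a 50% overlap and 85.16% for peaks above the median.

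Matched on length, the odds ratios for contact partners reversed to 0.775, 0.735 and 0.805 for higher regions at 2 h, 8 h and 23 h and to 0.886 for lower regions at 2 h, and those of lower regions at 8 h and 23 h, 1.067 and 1.099, no longer passed; longer regions overlap more fragments. With scores above the median the value of lower regions at 2 h was 1.118 and no longer passed. The ratio of 2.041 for contacts stayed above 1 and past the test in 5 alternatives, from 1.158 to 2.24. The 6 odds ratios for captured fragments stayed below 1 and past the test when matched on length. For named regions 764 values stayed past the test in the same direction and 51 no longer passed, 37 of these on tags per kb; chr5:172723414–172729649 at 23 h reversed there, to 0.014. Alternatives for gene lists and motifs were not run. Of 67 simulated 1.5-fold changes at 2 h 4.5% were recovered, 13.4% with libraries 10 times as deep and 28.4% with 4 libraries per time. Small changes that did not pass are thus not shown to be absent. With 200 regions changed in the simulation against 3054 called in the data, the simulated threshold was stricter. These shares may therefore be low for the data.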

Other observations

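The windows were picked after the result was seen; the tests of neighbours and of shared captured fragments were chosen before their results were seen.

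Changed regions lay in clusters along the chromosomes. In the window 10000001 to 11000000 of chromosome 16, 10 of 17 tested regions were lower at 2 h and none higher, among them chr16:10421140–10427824. In the window 12000001 to 13000000 of chromosome 12, 8 of 23 tested regions were higher at 2 h and none lower, and in the window 23000001 to 24000000 of X 7 of 8 were higher. At 23 h, 10 of 32 tested regions in the window 26000001 to 27000000 of chromosome 6 were lower. Other windows with many calls were mixed. In the window 52000001 to 53000000 of chromosome 20, 8 of 22 were lower at 2 h and 3 higher. In the window 126000001 to 127000000 of chromosome 8, 7 of 14 were higher at 23 h and 2 lower.

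Calls were more frequent among broad regions, at smaller folds and in no constant direction. Broad regions hold more tags, so smaller folds pass there; with no match on tags or level, the shares do not show that broad regions changed more often. Of the 687 regions with at least 10 kb called at 0 h, 20.5% were higher and 25.3% lower at 2 h, with median log2 fold changes of 0.52 and -0.52. At 8 h 9.6% were higher and 10.9% lower, and at 23 h 20.2% and 14.3%. Of the 7466 regions with less than 2 kb called, 6.8% were higher and 1.5% lower at 2 h, with medians of 1.54 and -1.62, 3.4% and 0.3% at 8 h, and 5.7% and 0.6% at 23 h; a region near the caller's minimum length has little room to fall and still be called in all libraries. Of the 23 regions with opposite calls (3 or 6 for 2 h and 23 h with a separate 0 h library for each time), 18 were lower at 2 h and higher at 23 h, 1 was lower at 2 h and 8 h and higher at 23 h, and 4 were higher at 2 h and lower at 23 h. At chr20:48994255–49026293, a region of 32.04 kb, 1 of these 23, the level was 303.2 ± 3.07 CPM at 0 h, 198.9 ± 0.426 at 2 h, 277.0 ± 11.1 at 8 h and 359.3 ± 27.6 at 23 h (23 h log2 0.24 against 0 h, adjusted p = 0.0406 in edgeR). Its called length was 29.1, 23.75, 27.23 and 26.3 kb, at 10.4, 8.45, 10.2 and 14.2 CPM per kb.

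The hypothesis that regions of like direction lie near each other was tested by 1000 permutations of the calls within chromosomes. At 2 h 44.3% of higher regions had another higher region 10 to 100 kb away, against 24.5% on average in permutations, and 43.8% of lower regions had another lower region there, against 25.4%. Of the higher regions 13.1% had a lower region at that distance, against 24.7%. Each permutation p was 0.002, the smallest they can give, and 0.002 after adjustment over the 9 tests. At 8 h the shares were 30.7% against 13.7%, 25.9% against 11.3% and 6.3% against 10.9%, and at 23 h 41.8% against 22.5%, 31.8% against 17.1% and 8.6% against 16.9%. The values are consistent with domains that respond together. Regions called apart within a single broad acetylated domain could give the first 2 shares too, and were not separated from distinct elements.

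The hypothesis that regions contacting the same captured fragment change together was tested on 5873 pairs against pairs at the same distance that share none. At 2 h the correlation of log2 fold changes over pairs was 0.08 against 0.039, a mean difference over 21 chromosomes of 0.04 ± 0.141 (SD), higher in 11 of 21 (permutation p = 0.207, adjusted 0.207). At 8 h and 23 h the differences were 0.042 and 0.03 (permutation p = 0.0788 and 0.119, adjusted 0.178 for both). None passed, and 12912 pairs had no control pair at the same distance, so the hypothesis stays open.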
